A study of Homo sapiens with 18 samples.

How the data were processed

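Ribosome footprints were sequenced from HCT116 cells in 18 libraries that fall into 6 groups of 3. Per the labels, cells received a nontargeting siRNA (siControl), or a pool of siRNAs at 75 nM against IGF2BP2 (siIGF2BP2) or IGF2BP3 (siIGF2BP3), for 48 h, and then tunicamycin (TM) at 5 µg/mL or its solvent DMSO for 4 h. The concentration of the nontargeting siRNA is not given separately. Per the labels' protocols, lysates were brought to equal RNA concentration and digested with nucleases, monosomes were collected from sucrose gradients, and ribosomal RNA was depleted after adapter ligation. The adapter carried a random molecular identifier and a sample index, so that samples could be joined during library preparation.

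The deposited values are whole-number read counts per gene in 1 table, identified by Ensembl gene ID, with no normalization by the authors recorded. Per the submitters' processing notes, cutadapt 5.0, UMI-tools 1.1.6, STAR 2.7.5c and featureCounts 2.0.1 were used with genome build hg38. The notes name these tools without their order or settings. Whether counting used strand, which feature was counted and which annotation was used is not given in the sources used here, so counts of overlapping, antisense or near-identical genes are uncertain. Footprint counts reflect ribosome occupancy, to which both the amount of an mRNA and its translation contribute, and matched RNA-seq was not used here.

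The table holds 60660 genes, of which 41991 had at least 1 count. Each of the 18 columns was matched to its sample by name. No replicates had identical values, and chi-square per degree of freedom between replicates of a group ranged from 1.77 to 4.11, so all were kept as separate libraries. The available RefSeq table lists 59792 genes with symbols and 0 with an Ensembl ID, and the files do not pair IDs with names. Genes are therefore given by ID, at most 2 higher and 2 lower per comparison. The check of the siRNA targets, the tests of gene lists chosen before the data were examined and the restriction to protein-coding genes were not run for this reason.

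Counts were tested with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 loaded. TMM factors were computed after the filterByExpr filter, which left 17533 genes holding 99.4% to 99.7% of each library's counts. All 18 libraries entered 1 quasi-likelihood model with a mean per group and no covariate, so that groups shared 1 estimate of the spread. The common dispersion was 0.0068, a biological coefficient of variation of 0.0825. Each comparison was tested with edgeR's quasi-likelihood F test and Benjamini-Hochberg adjustment over all 17533 genes, with 0.05 as the threshold on the adjusted p. All adjusted p-values of single genes come from that test unless DESeq2 is named. Normalized values are CPM, counts scaled to a common library size with the TMM factors, and are given as mean ± SD over 3 libraries.

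The comparisons were TM against DMSO within each siRNA, each knockdown against siControl within each treatment, the 2 knockdowns against each other, and the interaction of each knockdown with TM. The rule for named genes was written before the data were examined. It takes, among genes past the threshold with a mean of at least 5 CPM and with all 3 libraries of one group above all 3 of the other, those with the largest rise and fall. Where fewer than 3 pass in a comparison, it takes the 3 genes of lowest p. Chance alone separates 3 libraries from 3 in this way for 10% of genes. Where a group had 0 counts of a gene, the fold is a lower bound against 3 counts over the whole group, and where it had 1 to 3 counts the ratio is given with an exact 95% counting interval. Intervals and floors cover counting error only.

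Total counts ranged from 19634 in the library labelled siIGF2BP2_DMSO replicate 2 to 11278862 in siControl_TM replicate 1. For genes of at least 5 CPM the median standard error of a log2 fold change was between 0.12 and 0.15 in comparisons of 2 groups, and 0.18 (siIGF2BP3) and 0.20 (siIGF2BP2) in the interactions. The procedure was tested on simulated data, in which 200 of the 17533 genes were changed by known amounts per comparison. Of the genes changed by 1 on the log2 scale, edgeR recovered 70.1% for TM in siControl, 73.1% for TM in siIGF2BP3, 67.2% for TM in siIGF2BP2, 71.6% for siIGF2BP3 in DMSO, 76.1% for siIGF2BP3 in TM, 64.2% for siIGF2BP2 in DMSO and 71.6% for siIGF2BP2 in TM. The corresponding shares were 76.1% and 67.2% for the knockdowns against each other in DMSO and in TM. They were 56.7% for the siIGF2BP3 interaction and 49.3% for the siIGF2BP2 interaction. Of genes changed by 0.5, between 4.48% (siIGF2BP2 interaction) and 40.3% (siIGF2BP3 in DMSO) were recovered. False calls with edgeR, in the order of these comparisons, were 12 of 140, 4 of 140 and 7 of 121 (TM), 17 of 151 and 18 of 153 (siIGF2BP3), 10 of 132 and 6 of 134 (siIGF2BP2), 13 of 146 and 1 of 119 (knockdowns against each other), and 16 of 120 and 4 of 88 (interactions), so that in 7 of the 11 more than 5% of the calls were false. DESeq2 made 0 to 2 false calls in each, and recovered fewer of the changed genes. Of genes changed by 1 it recovered 35.8% to 49.3% in comparisons of 2 groups and 17.9% in each interaction.

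Replicate numbers come from the labels, which do not say what they share. They were taken to pair libraries where the deviations of same-numbered libraries from their group means correlated above 0.1 across genes for all 3 numbers. For replicates 1, 2 and 3 these correlations were 0.196, 0.145 and 0.218 for TM in siControl, 0.257, 0.192 and 0.147 for TM in siIGF2BP3, and 0.185, 0.166 and 0.221 for siIGF2BP3 against siControl in TM. They were 0.204, 0.132 and 0.217 for siIGF2BP2 against siControl in TM, and 0.276, 0.170 and 0.262 for the knockdowns against each other in TM. In these 5 comparisons the count with the replicate number as a block is given beside the count without it.

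Alternatives chosen before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter beyond 1 count, a filter at a mean of 5 CPM, only the compared groups in the model, the replicate block, a further threshold of 1 on the absolute log2 fold change, and leaving out each compared library in turn. Refits without the library of lowest total, alone, with the block and with DESeq2, were added after seeing the data where they were not already listed. Overlaps of comparisons are given beside the number expected for independent lists, and correlations of fold changes across genes beside 20 simulations of unchanged groups.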

Results

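Ribosome profiling, which sequences the mRNA fragments protected by ribosomes, was carried out in HCT116, a human colorectal carcinoma cell line. The study addressed how knockdown of IGF2BP2 or IGF2BP3, members of a family of RNA-binding proteins, affects cells with and without endoplasmic reticulum stress. Stress was induced with tunicamycin (TM), an inhibitor of N-linked glycosylation that causes unfolded proteins to accumulate in the endoplasmic reticulum, and DMSO served as the solvent control. There were 3 libraries for each of 6 groups. Total counts ranged from 1931619 to 7752664 in siControl_DMSO, from 3279557 to 11278862 in siControl_TM, from 4383677 to 8798212 in siIGF2BP3_DMSO, from 3395541 to 10760520 in siIGF2BP3_TM and from 1793076 to 6053915 in siIGF2BP2_TM. In siIGF2BP2_DMSO the highest total was 8197657, and the library labelled siIGF2BP2_DMSO replicate 2 had 19634 counts.

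**Figure D1:**
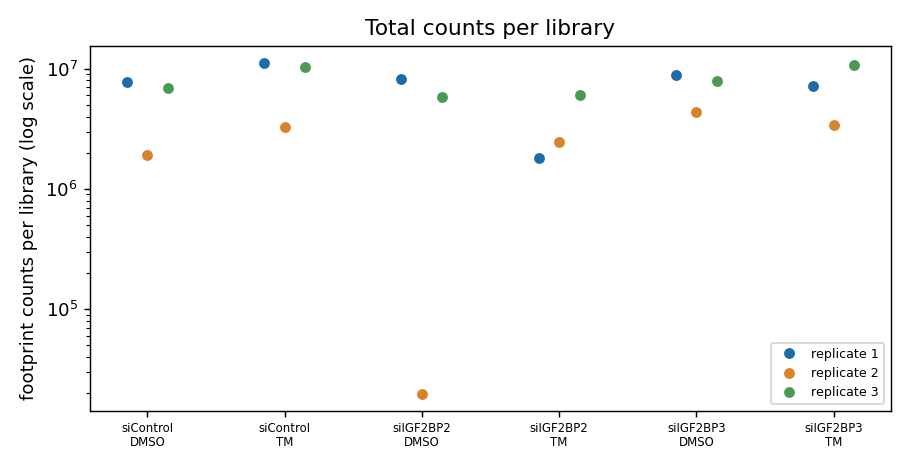
Total footprint counts per library on a logarithmic axis, 1 point per library, coloured by replicate number. The library labelled siIGF2BP2_DMSO replicate 2 lies at 19634, below the other 17 libraries, which lie between 1793076 and 11278862.

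The library labelled siIGF2BP2_DMSO replicate 2 had counts in 5883 genes, and 11762 of the 17533 tested genes had none in it. Genes raised at least 4-fold by TM in the other siRNA arms held 111 of its counts, against 26.3 expected from replicates 1 and 3 of its group, which corresponds to 51.6% of counts with the TM profile (95% counting interval 39.6% to 65.4%). The same estimate lay between -0.69% and 0.57% in the other libraries labelled DMSO. For this reason levels in siIGF2BP2_DMSO are given for replicates 1 and 3. The labels call the libraries biological replicates, each from its own well, without saying whether the wells came from separate cultures, so p-values measure the spread between these libraries.

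**Figure D2:**
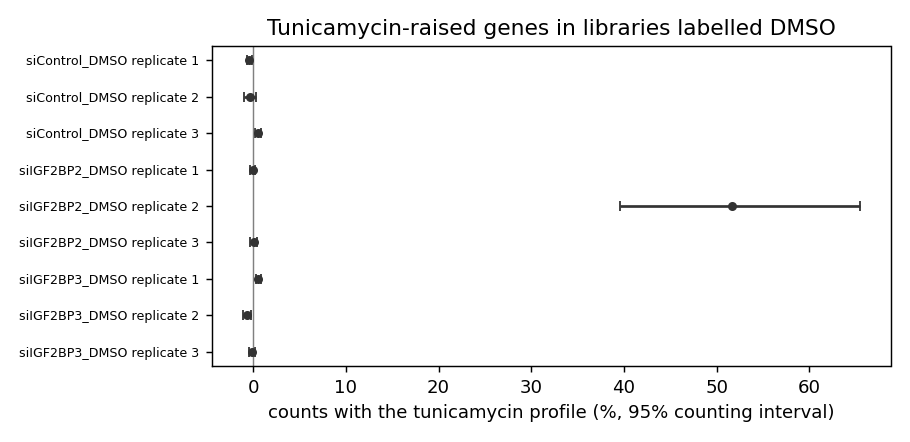
Estimated percentage of counts that follow the TM profile in each library labelled DMSO, from 40 genes raised at least 4-fold by TM in siControl and siIGF2BP3, with 95% counting intervals. The library labelled siIGF2BP2_DMSO replicate 2 lies at 51.6% and the others lie between -0.69% and 0.57%.

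The response to TM was first measured in cells with the nontargeting siRNA. Footprints of 1778 genes rose and those of 1354 fell, and 386 of the raised and 139 of the lowered genes changed at least 2-fold. ENSG00000128965 rose from 2.68 ± 0.58 CPM in DMSO to 126 ± 11.1 CPM in TM (SD, n = 3), a log2 fold change of 5.68 (SE 0.19, adjusted p = 5.54e-16). ENSG00000175197 rose by 5.62 on the log2 scale (SE 0.25, adjusted p = 6.30e-14), from 1.61 ± 1.48 to 52.0 ± 6.76 CPM. Among lowered genes, ENSG00000204389 fell from 289 ± 19.5 to 54.55 ± 2.36 CPM (log2 fold change -2.41, SE 0.10, adjusted p = 3.83e-14) and ENSG00000204390 from 22.4 ± 1.47 to 4.09 ± 0.55 CPM (log2 fold change -2.48, SE 0.16, adjusted p = 7.73e-11). In total 2641 called genes with at least 5 CPM had no overlap between the groups. With the replicate number as a block 4815 genes passed, including all 3132 of the unblocked test, and DESeq2 on all libraries called 592, or 2507 without the library labelled siIGF2BP2_DMSO replicate 2.

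**Figure D3:**
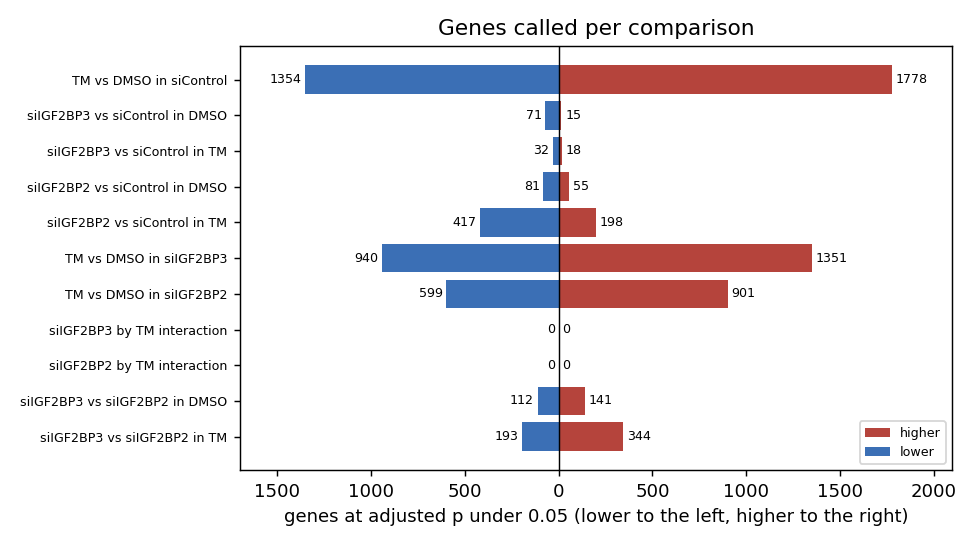
Number of genes past the threshold in each comparison (edgeR, Benjamini-Hochberg adjusted p under 0.05), with lower genes to the left and higher genes to the right. TM against DMSO in siControl had 1778 higher and 1354 lower genes, and both interactions had 0.

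IGF2BP3 knockdown was then compared with siControl without stress. Footprints of 71 genes were lower and those of 15 were higher, and the median log2 fold change of the lower genes was -1.54, with 51 of them lower by at least 2-fold. ENSG00000136231 fell from 73.4 ± 1.70 CPM in siControl to 11.4 ± 0.39 CPM in siIGF2BP3 (log2 fold change -2.67, SE 0.12, adjusted p = 3.84e-12). ENSG00000235008 fell from 28.1 ± 1.79 to 2.86 ± 0.85 CPM (log2 fold change -3.23, SE 0.17, adjusted p = 3.25e-11). ENSG00000171951 rose from 8.77 ± 0.63 to 26.4 ± 1.73 CPM (log2 fold change 1.61, SE 0.15, adjusted p = 8.13e-07). ENSG00000264663 rose by 0.98 (SE 0.17, adjusted p = 0.00706), a call lost without siControl_DMSO replicate 1 (adjusted p = 0.139) and with DESeq2 on all libraries, within a range from 3.48e-06 to 1 over the alternatives. In simulated data 17 of the 151 edgeR calls of this comparison were false, and 1 of 77 with DESeq2. Of genes changed by 1 on the log2 scale, edgeR recovered 71.6% and DESeq2 35.8%. The 86 calls became 24 without siControl_DMSO replicate 1, 41 without siControl_DMSO replicate 3, and 36, 28 and 23 without siIGF2BP3_DMSO replicates 1, 2 and 3. They became 293 with only the compared groups in the model, 568 without the filter on low counts, and 15 with DESeq2 on all libraries, or 100 with DESeq2 without the library labelled siIGF2BP2_DMSO replicate 2.

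Under TM, IGF2BP3 knockdown lowered 32 genes and raised 18. The same 2 genes led the fall: ENSG00000136231 was at 12.2 ± 2.57 CPM against 69.0 ± 5.02 CPM in siControl (log2 fold change -2.57, SE 0.12, adjusted p = 8.37e-12), and ENSG00000235008 at 2.99 ± 0.91 against 23.5 ± 1.71 CPM (log2 fold change -3.08, SE 0.18, adjusted p = 1.03e-10). The fall of ENSG00000136231 was not limited to this knockdown. It was also called lower in siIGF2BP2 against siControl in TM (log2 fold change -0.55, SE 0.11, adjusted p = 0.00658), and not in DMSO (-0.40, SE 0.11, adjusted p = 0.11). ENSG00000171951 rose again, from 11.2 ± 2.66 to 29.6 ± 1.67 CPM (log2 fold change 1.31, SE 0.13, adjusted p = 2.94e-06). ENSG00000132915 rose from 0.90 ± 0.17 to 19.8 ± 6.48 CPM (log2 fold change 4.45, SE 0.56, adjusted p = 1.08e-04), a call that DESeq2 did not make on all libraries (adjusted p = 0.528) but made without the library labelled siIGF2BP2_DMSO replicate 2 (9.89e-07), within a range from 6.86e-55 to 0.528 over the alternatives. Of the 71 genes lowered in DMSO, 70 were lower in TM and 15 were called there, against 0.13 expected for independent lists. Of the 15 genes raised in DMSO, all 15 were higher in TM and 5 were called, against 0.0154 expected. With the replicate number as a block 321 genes passed, without the filter on low counts 299, with only the compared groups in the model 30, and with DESeq2 on all libraries 9, or 69 without the library labelled siIGF2BP2_DMSO replicate 2. In simulated data 18 of the 153 edgeR calls of this comparison were false, and 0 of 83 with DESeq2. Of genes changed by 1 on the log2 scale, edgeR recovered 76.1% and DESeq2 40.3%. The 50 calls became 20 without siControl_TM replicate 1, and 22, 29 and 19 without siIGF2BP3_TM replicates 1, 2 and 3.

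IGF2BP2 knockdown without stress lowered 81 genes and raised 55. ENSG00000073792 was at 74.6 ± 4.30 CPM in siControl and at 11.04 and 13.8 CPM in replicates 1 and 3 of siIGF2BP2 (log2 fold change -2.60, SE 0.14, adjusted p = 8.12e-11). ENSG00000225603 was at 15.9 ± 1.72 CPM in siControl and at 2.18 and 2.93 CPM in these replicates (log2 fold change -2.62, SE 0.23, adjusted p = 6.25e-07). ENSG00000255198 rose from 28.99 ± 1.98 CPM to 56.0 and 59.1 CPM (log2 fold change 1.01, SE 0.11, adjusted p = 1.01e-05), and ENSG00000088727 by 0.98 (SE 0.15, adjusted p = 7.43e-04), the latter a call that DESeq2 did not make on all libraries but made without the library labelled siIGF2BP2_DMSO replicate 2 (adjusted p = 0.00356), within a range from 1.53e-04 to 1 over the alternatives. The 136 calls became 76 and 65 without siControl_DMSO replicates 1 and 3, and 38 and 83 without siIGF2BP2_DMSO replicates 1 and 3. Without the library labelled siIGF2BP2_DMSO replicate 2 there were 186 calls, including 135 of the 136, without the filter on low counts 244, and with DESeq2 21 on all libraries, or 171 without that library.

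Under TM, IGF2BP2 knockdown lowered 417 genes and raised 198. ENSG00000073792 fell from 74.0 ± 3.43 to 10.1 ± 2.51 CPM (log2 fold change -2.75, SE 0.14, adjusted p = 3.27e-11) and ENSG00000225603 from 18.5 ± 1.78 to 2.66 ± 1.19 CPM (log2 fold change -2.57, SE 0.23, adjusted p = 3.12e-07). ENSG00000036565 had 253 counts in siIGF2BP2_TM and 0 in siControl_TM, at least 199-fold higher (adjusted p = 6.97e-05), and ENSG00000145642 rose from 0.35 ± 0.33 to 28.1 ± 26.8 CPM (log2 fold change 5.75, SE 0.70, adjusted p = 4.40e-05). The bound was 106 without siIGF2BP2_TM replicate 1, 351 without replicate 3 of that group, and 109 and 116 without siControl_TM replicates 1 and 3. The log2 fold change of ENSG00000145642 was 4.72 without siIGF2BP2_TM replicate 1, and that of ENSG00000225603 was -3.25 without replicate 3. DESeq2 on all libraries called neither rise (adjusted p = 0.729 and 0.577), and without the library labelled siIGF2BP2_DMSO replicate 2 it called ENSG00000145642 (7.84e-06) and not ENSG00000036565 (0.135); over the alternatives adjusted p ranged from 4.05e-84 to 0.729 for ENSG00000036565 and from 4.17e-54 to 0.577 for ENSG00000145642. Of the genes called in DMSO, 67 of 81 lowered genes and 30 of 55 raised genes were called in the same direction in TM, against 1.93 and 0.62 expected for independent lists. With the replicate number as a block 1659 genes passed, with only the compared groups in the model 187, and with DESeq2 46 on all libraries, or 531 without the library labelled siIGF2BP2_DMSO replicate 2. The 615 calls became 268 without siControl_TM replicate 1, and 327 and 317 without siIGF2BP2_TM replicates 2 and 3.

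**Figure D4:**
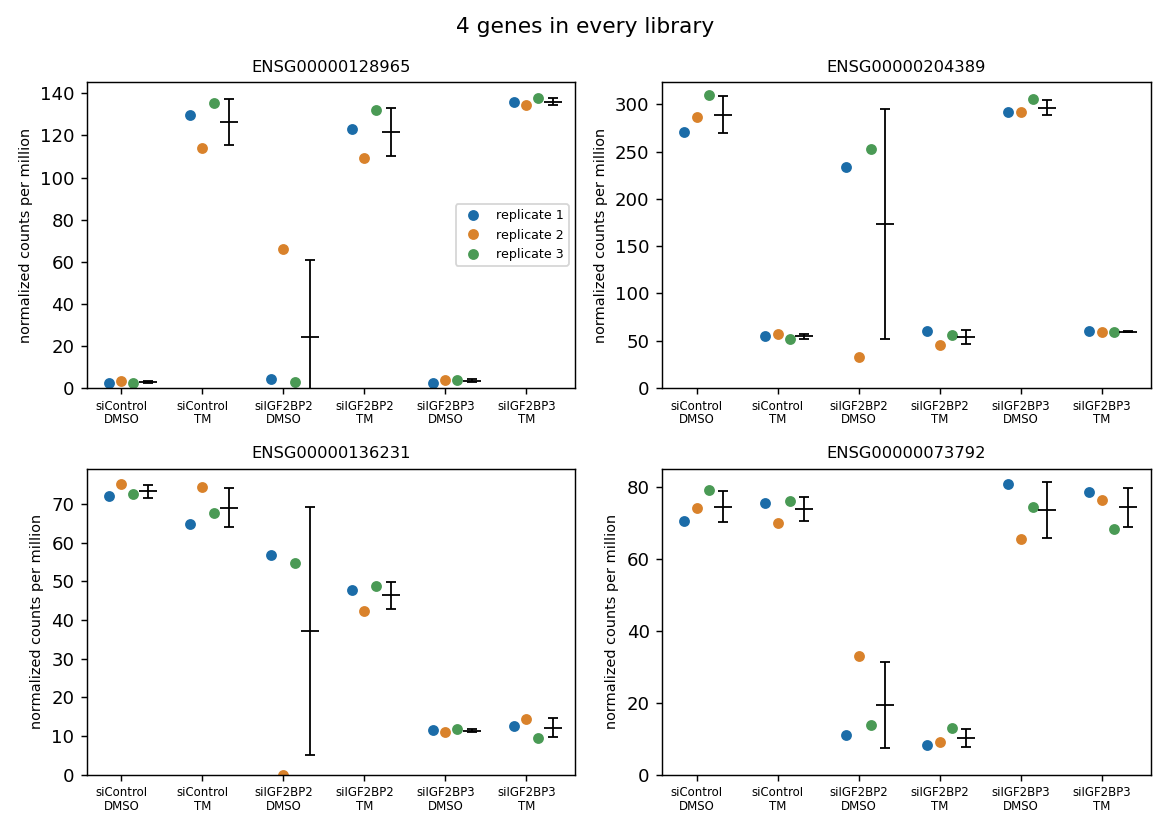
Normalized CPM of 4 genes in every library, with points coloured by replicate number and horizontal bars with whiskers for mean ± SD (n = 3). ENSG00000128965 rose and ENSG00000204389 fell with TM. ENSG00000136231 was at 11.4 and 12.2 CPM in the siIGF2BP3 groups, and at 46.4 CPM in siIGF2BP2_TM against 69.0 CPM in siControl_TM. ENSG00000073792 was at 10.1 CPM in siIGF2BP2_TM. The points of the library labelled siIGF2BP2_DMSO replicate 2 rest on 2, 1, 0 and 1 counts of the 4 genes, in the order named.

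The TM response was also measured with IGF2BP3 knocked down, where 1351 genes rose and 940 fell. ENSG00000128965 rose from 3.33 ± 0.70 to 136 ± 1.61 CPM (log2 fold change 5.38, SE 0.16, adjusted p = 1.45e-16) and ENSG00000175197 from 1.22 ± 0.19 to 42.6 ± 4.18 CPM (log2 fold change 5.13, SE 0.23, adjusted p = 7.39e-14). ENSG00000204390 fell by 2.32 (SE 0.16, adjusted p = 2.26e-10) and ENSG00000204389 by 2.31 on the log2 scale (SE 0.10, adjusted p = 4.76e-14). Of the raised genes 1042 were also raised in siControl, and of the lowered genes 646 were also lowered, against 137 and 72.6 expected for independent lists, and 0 genes were called in opposite directions. With the replicate number as a block 3907 genes passed, including all 2291 of the unblocked test, and DESeq2 called 401 on all libraries, or 1849 without the library labelled siIGF2BP2_DMSO replicate 2. Without siIGF2BP3_DMSO replicate 3 there were 1521 calls.

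With IGF2BP2 knocked down, TM raised 901 genes and lowered 599. ENSG00000175197 rose from 0.49 and 0.69 CPM in replicates 1 and 3 of siIGF2BP2_DMSO to 34.6 ± 6.996 CPM (log2 fold change 5.92, SE 0.32, adjusted p = 4.86e-12). ENSG00000036565 had 253 counts in TM and 1 in DMSO, a ratio of 351 (95% counting interval 62.4 to 13904, adjusted p = 1.08e-04), a call that DESeq2 did not make with or without the library labelled siIGF2BP2_DMSO replicate 2 (adjusted p = 1 and 0.264, range over the alternatives 1.06e-56 to 1). The ratio was 187 and 618 without siIGF2BP2_TM replicates 1 and 3, 145 without siIGF2BP2_DMSO replicate 1, and at least 68.7 without siIGF2BP2_DMSO replicate 3, which held the count in DMSO. ENSG00000204388 fell from 107 and 122 CPM to 22.2 ± 2.64 CPM (log2 fold change -2.31, SE 0.12, adjusted p = 1.70e-12) and ENSG00000256356 from 506 and 549 CPM to 132 ± 10.4 CPM (log2 fold change -1.95, SE 0.10, adjusted p = 2.65e-12). The 2 genes named as lowered in siControl also fell here, in the order given there by -2.15 (adjusted p = 3.62e-12) and -2.39 (adjusted p = 5.01e-08) on the log2 scale. They were not named because the rule includes the library labelled siIGF2BP2_DMSO replicate 2, in which they did not lie above the TM libraries. Of the raised genes 740 were also raised in siControl, and of the lowered genes 409 were also lowered, against 91.4 and 46.3 expected for independent lists, and 2 genes were called in opposite directions. The 1500 calls became 780 without siIGF2BP2_DMSO replicate 1, 987 without siIGF2BP2_DMSO replicate 3 and 1665 without the library labelled siIGF2BP2_DMSO replicate 2. They became 859 with only the compared groups in the model and 299 with DESeq2 on all libraries, or 1236 with DESeq2 without the library labelled siIGF2BP2_DMSO replicate 2.

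Whether a knockdown changed the TM response was tested as an interaction. For genes raised at least 2-fold by TM in siIGF2BP2, a list of 260 chosen in libraries outside the siIGF2BP3 comparison, the median log2 response was 1.40 in siControl and 1.35 in siIGF2BP3, and the mean interaction was -0.04 (2-sided exact permutation p = 0.165, adjusted p = 0.22 over 4 such tests). For the 287 genes raised at least 2-fold in siIGF2BP3, the median response was 1.39 in siControl and 1.29 in siIGF2BP2, in the model of all 18 libraries. Their mean interaction, without the library labelled siIGF2BP2_DMSO replicate 2, was -0.11 (2-sided exact permutation p = 0.06, adjusted p = 0.16). A negative interaction is a smaller rise for raised genes and a larger fall for lowered genes. For lowered genes the mean interaction was 0.01 over 126 genes for siIGF2BP3 (exact permutation p = 0.875, adjusted p = 0.875) and -0.15 over 100 genes for siIGF2BP2 (exact permutation p = 0.08, adjusted p = 0.16). These permutations exchange libraries within a treatment whatever their replicate number, which carries effects of siRNA into the interaction, so a p above the threshold here is no measure of an absent change. The SE between libraries of the 4 mean interactions was 0.0225, 0.0289, 0.0668 and 0.0813 in that order. Within numbers 1, 2 and 3 the interaction for siIGF2BP3 was -0.07, -0.06 and -0.01 for raised genes and -0.01, 0.03 and 0.02 for lowered genes. Within numbers 1 and 3 it was -0.13 and -0.10 for raised and -0.11 and -0.09 for lowered genes for siIGF2BP2. With 3 or 2 numbers an exact sign-flip test cannot give a p under 0.25 or 0.5.

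**Figure D5:**
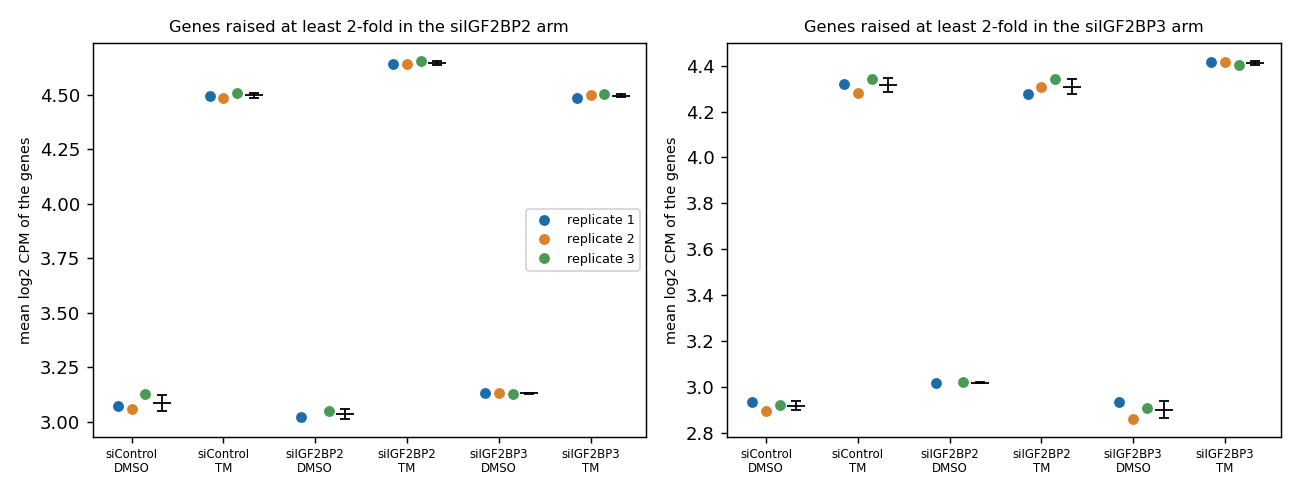
Mean log2 CPM in each library of the 260 genes raised at least 2-fold by TM in siIGF2BP2 (left) and of the 287 genes raised at least 2-fold by TM in siIGF2BP3 (right), with mean ± SD per group; the library labelled siIGF2BP2_DMSO replicate 2 is left out, so that group has 2 points. The TM libraries lie above the DMSO libraries of every siRNA.

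Gene by gene, edgeR called 0 genes in the siIGF2BP3 interaction, with 749 at an unadjusted p under 0.05, and 0 in the siIGF2BP2 interaction, with 1165. DESeq2 also called 0 in both on all libraries, and 1 and 4 without the library labelled siIGF2BP2_DMSO replicate 2. In simulated data DESeq2 recovered 17.9% of genes changed by 1 on the log2 scale in each interaction, so its 0 calls do not show an absent change. Among genes of at least 5 CPM the lowest p for siIGF2BP3 belonged to ENSG00000214671 (log2 interaction 0.71, SE 0.14, adjusted p = 0.459), ENSG00000104267 (-0.89, SE 0.20, adjusted p = 0.766) and ENSG00000246228 (-1.14, SE 0.27, adjusted p = 0.980). For siIGF2BP2 it belonged to ENSG00000227852 (0.69, SE 0.13, adjusted p = 0.137), ENSG00000259932 (-3.23, SE 0.66, adjusted p = 0.244) and ENSG00000206737 (-1.97, SE 0.41, adjusted p = 0.244), and all 3 passed without siIGF2BP2_DMSO replicate 3 (adjusted p = 0.0135, 5.90e-04 and 0.00321). Over the alternatives their adjusted p ranged from 0.00213, 4.83e-63 and 5.27e-10 to 1. The siIGF2BP3 interaction had 1 call without siIGF2BP3_TM replicate 3 and 104 without the filter on low counts. The siIGF2BP2 interaction had 2 calls without siControl_TM replicate 3, 59 without siIGF2BP2_DMSO replicate 3 and 214 without the filter. Without siIGF2BP2_DMSO replicate 3 that group holds replicate 1 and the library labelled siIGF2BP2_DMSO replicate 2, which has 19634 counts. These 59 calls and the passes of the 3 named genes therefore rest largely on replicate 1 of that group. ENSG00000259932 was at 75.6 CPM in siIGF2BP2_DMSO replicate 1 and 13.3 CPM in the replicate left out. A block for the replicate number in edgeR gave 11 calls in the siIGF2BP3 interaction, including ENSG00000214671 (adjusted p = 0.0259), and 179 in the siIGF2BP2 interaction, including its 3 named genes, or 8 and 150 without the library labelled siIGF2BP2_DMSO replicate 2. The numbers paired the libraries in 3 of the 4 comparisons within the siIGF2BP3 interaction, all but siIGF2BP3 in DMSO, and in 2 of the 4 within the siIGF2BP2 interaction, TM in siControl and siIGF2BP2 in TM. In the comparisons with siIGF2BP2_DMSO the check included the library labelled siIGF2BP2_DMSO replicate 2, so it cannot decide on pairing there.

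The knockdowns were also compared with each other. In DMSO, 141 genes were higher and 112 lower in siIGF2BP3 than in siIGF2BP2. ENSG00000225603 (log2 difference 2.72, SE 0.23, adjusted p = 1.02e-07) and ENSG00000073792 (2.59, SE 0.14, adjusted p = 6.16e-11) were higher, and ENSG00000104267 was lower, at 9.71 ± 0.59 CPM in siIGF2BP3 against 46.2 and 39.1 CPM in replicates 1 and 3 of siIGF2BP2 (-2.15, SE 0.13, adjusted p = 2.16e-10). ENSG00000264169 was lower by -1.24 (SE 0.27, adjusted p = 0.0184), a call lost without siIGF2BP2_DMSO replicate 1 (adjusted p = 0.301), without siIGF2BP3_DMSO replicate 2 (0.0567) or replicate 3 (0.124), and with DESeq2 (0.471 on all libraries, 0.109 without the library labelled siIGF2BP2_DMSO replicate 2), within a range from 6.60e-24 to 0.471 over the alternatives. The 253 calls became 102 and 91 without siIGF2BP2_DMSO replicates 1 and 3, and 153, 135 and 109 without siIGF2BP3_DMSO replicates 1, 2 and 3. They became 461 with only the compared groups in the model, 447 without the filter, and 37 with DESeq2 on all libraries, or 264 with DESeq2 without the library labelled siIGF2BP2_DMSO replicate 2.

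In TM, 344 genes were higher and 193 lower in siIGF2BP3 than in siIGF2BP2, and 107 of the higher and 64 of the lower genes in DMSO were among them, against 2.77 and 1.23 expected for independent lists. ENSG00000073792 (log2 difference 2.75, SE 0.14, adjusted p = 1.92e-11) and ENSG00000225603 (2.41, SE 0.23, adjusted p = 6.61e-07) were higher. ENSG00000036565 had 0 counts in siIGF2BP3_TM and 253 in siIGF2BP2_TM, at least 171-fold lower (adjusted p = 6.48e-05), and ENSG00000145642 had 1 against 201 counts, a ratio of siIGF2BP2 to siIGF2BP3 of 407 (95% counting interval 72.2 to 16157, adjusted p = 1.44e-05). Without siIGF2BP2_TM replicates 1 and 3 the bound was 91.0 and 301 and the ratio 244 and 679. Without siIGF2BP3_TM replicates 1 and 3 the bound was 114 and 83.5 and the ratio at least 90.3 and 199, and ENSG00000225603 was at 3.09 without siIGF2BP2_TM replicate 3. DESeq2 on all libraries called neither (adjusted p = 0.666 and 0.0657), and without the library labelled siIGF2BP2_DMSO replicate 2 it called ENSG00000145642 (7.77e-07) and not ENSG00000036565 (0.141); over the alternatives adjusted p ranged from 1.16e-78 to 0.666 for ENSG00000036565 and from 1.50e-61 to 0.0657 for ENSG00000145642. With the replicate number as a block 1661 genes passed, without the filter 914, with only the compared groups in the model 323, and with DESeq2 71 on all libraries, or 516 without the library labelled siIGF2BP2_DMSO replicate 2. The 537 calls became 355 and 293 without siIGF2BP3_TM replicates 2 and 3.

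Across the 17533 tested genes, which are not independent replicates, the knockdown effects in DMSO correlated with Pearson's r of 0.541 and Spearman's rho of 0.469, and those in TM with 0.294 and 0.305. Each correlation compares effects measured against the same siControl libraries. Unchanged groups simulated against those controls gave a mean r of 0.493 in DMSO and 0.408 in TM. The simulated libraries were drawn independently, although the replicate numbers paired the libraries of the knockdown comparisons in TM, so the simulated values leave out that pairing. The covariance was 0.0673 in DMSO against 0.0365 simulated, and 0.0347 in TM against 0.0287 simulated. No gene was called lower by both knockdowns in DMSO and 1 was called higher, against 0.328 and 0.0471 expected for independent lists, and 1 was called in opposite directions. In TM 6 genes were called lower by both and 4 higher, against 0.761 and 0.203 expected, and 3 were called in opposite directions. The simulated groups shared at most 1 call in DMSO and 0 in TM over 20 simulations. No gene was changed in them, so there were few calls to share. They therefore cannot tell how far the shared siControl libraries raise these overlaps. Between effects that share no library, r was 0.427 for siIGF2BP3 in DMSO and in TM and 0.169 for siIGF2BP2 in DMSO and in TM. Across knockdowns it was 0.191 for siIGF2BP2 in DMSO with siIGF2BP3 in TM and -0.107 for siIGF2BP3 in DMSO with siIGF2BP2 in TM. Among genes of at least 5 CPM these 4 values were 0.5002, 0.295, 0.198 and -0.193, and r between the knockdowns was 0.479 in DMSO and 0.220 in TM.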

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

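Refits without the library labelled siIGF2BP2_DMSO replicate 2 were chosen after the data were seen, except with edgeR and no block where that library was itself compared; the other alternatives were chosen before. With DESeq2 size factors or a filter at a mean of 5 CPM all 11 counts stayed within 1.5 times their values. The order below is TM in siControl, siIGF2BP3 in DMSO and in TM, siIGF2BP2 in DMSO and in TM, TM in siIGF2BP3 and in siIGF2BP2, the siIGF2BP3 and siIGF2BP2 interactions, and the knockdowns against each other in DMSO and in TM; the counts under the reported setting were 3132, 86, 50, 136, 615, 2291, 1500, 0, 0, 253 and 537. Without the library labelled siIGF2BP2_DMSO replicate 2, edgeR gave 3277, 61, 60, 186, 682, 2447, 1665, 0, 0, 304 and 634, all within 1.5 times. The DESeq2 Wald test gave 592, 15, 9, 21, 46, 401, 299, 0, 0, 37 and 71, all among the reported calls except 3 of the 37. Without the library labelled siIGF2BP2_DMSO replicate 2, DESeq2 gave counts within 1.5 times the reported ones except for 1 and 4 in the interactions. Most of the difference in counts between the tools thus went with that library. Without it, siIGF2BP3 in DMSO was the only comparison of 2 groups in which the tools differed by more than 1.5 times (61 with edgeR, 100 with DESeq2). The genes also differed in part, as 67 of those 100 were among the 86 reported calls. With no filter beyond 1 count, moved counts were 568 and 299 (siIGF2BP3 in DMSO and TM), 244 (siIGF2BP2 in DMSO), 104 and 214 (interactions), and 447 and 914 (knockdowns against each other). With only the compared groups in the model they were 293 and 30 (siIGF2BP3), 187 (siIGF2BP2 in TM), 859 (TM in siIGF2BP2), and 461 and 323 (knockdowns against each other). The cause was not tested for either.

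With the replicate number as a block the counts in that order were 4815, 870, 321, 640, 1659, 3907, 2479, 11, 179, 786 and 1661, and without the library labelled siIGF2BP2_DMSO replicate 2 they were 4932, 883, 344, 718, 1792, 3975, 2633, 8, 150, 843 and 1777. The cause was not tested. The numbers did not pair libraries by the rule used in siIGF2BP3 against siControl in DMSO (correlations 0.213, 0.114 and 0.0824 for replicates 1, 2 and 3), siIGF2BP2 against siControl in DMSO (0.0409, 0.0494 and 0.0915), TM in siIGF2BP2 (-0.0158, 0.00684 and 0.0996) and the knockdowns against each other in DMSO (0.0328, 0.0286 and 0.0455). Each library correlated best with its own number in all of these except TM in siIGF2BP2, a hint from the data and not from the design. Except for siIGF2BP3 against siControl in DMSO, these comparisons include siIGF2BP2_DMSO. The mean of that group holds the library labelled siIGF2BP2_DMSO replicate 2, in which 11762 of the 17533 tested genes had no count. The check was not repeated without that library, so it cannot decide on pairing in these comparisons. With the further threshold of 1 on the absolute log2 fold change, the counts of the comparisons of 2 groups were 525, 52, 15, 21, 83, 387, 386, 43 and 84, as that threshold by construction removes smaller changes.

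Leaving out each compared library in turn gave 2108 to 2870 for TM in siControl, 23 to 82 and 19 to 43 for siIGF2BP3 in DMSO and TM, 38 to 186 and 268 to 477 for siIGF2BP2 in DMSO and TM, 1521 to 1823 and 780 to 1665 for TM in siIGF2BP3 and siIGF2BP2, 0 to 1 and 0 to 59 for the interactions, and 91 to 304 and 293 to 471 for the knockdowns against each other. These refits have fewer libraries. The correlation of knockdown effects ranged from 0.441 (without replicate 1) to 0.569 (Pearson) and from 0.378 (without replicate 1) to 0.503 (Spearman) in DMSO, and from 0.277 to 0.373 (without replicate 1, Pearson) in TM; for genes of at least 5 CPM it was 0.220 in TM. Counted per named gene and setting, results for single genes kept direction and side of the threshold in 618 cases, passed only in the refit in 16 and no longer passed in 17, and none reversed. Settings in which a gene had no adjusted p are not among these. Of the counts of calls and the correlations of knockdown effects under the alternatives, 124 were classed as the same and 88 as moved. Depth limits the library labelled siIGF2BP2_DMSO replicate 2 most, with 19634 counts. The alternative restricted to protein-coding genes and those on gene lists were not run.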

Other observations

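Tests of the TM profile in the library labelled siIGF2BP2_DMSO replicate 2, of the mix of replicate 2 libraries, of its depth, of equal depth in TM, of the library difference in siIGF2BP2_TM and of the siIGF2BP2 effect against the TM response were chosen only after the result was seen, as were the refits without that library, except those with edgeR and no block in comparisons that include it. ENSG00000036565 and ENSG00000145642 were at 11.9 and 10.8 CPM or more in each siIGF2BP2_TM library and at most 0.17 and 1.11 CPM in the libraries of the other groups, leaving out the library labelled siIGF2BP2_DMSO replicate 2. By the same rule 1 gene stood out in siIGF2BP3_TM (at least 9.80 CPM there and at most 1.66 CPM elsewhere) and 0 in each of the other 4 groups. The levels of the first 2 in siIGF2BP2_TM replicates 1, 2 and 3 were 82.2, 16.6 and 11.9 CPM for ENSG00000036565 and 58.9, 14.5 and 10.8 CPM for ENSG00000145642.

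Genes lowered by IGF2BP2 knockdown in TM were compared with the TM response in siIGF2BP3, which shares no library with that effect. Of these, 110 of 417 were raised by TM, against 32.1 expected for independent lists, and 34 were lowered, against 22.4; of the 198 raised genes, 28 were lowered by TM, against 10.6 expected, and 15 were raised, against 15.3. Across 12732 genes of at least 5 CPM, which are not independent replicates, the correlation was close to 0, at -0.0429 (Pearson; -0.0845 to -0.00957 when each compared library was left out) and -0.0933 (Spearman). By the same measure against the TM response of the other knockdown, Pearson's r was -0.112 for siIGF2BP3 in TM (-0.162 to -0.00501), -0.123 for siIGF2BP3 in DMSO (-0.216 to 0.0337) and 0.0114 for siIGF2BP2 in DMSO (-0.0179 to 0.0413), with Spearman's rho of -0.0639, -0.0177 and 0.0169. Genes lowered by the knockdown and raised by TM numbered 3 (1.64 expected), 1 (3.65) and 19 (6.24) in these, and genes raised by it and lowered by TM 1 (0.615), 1 (0.512) and 5 (2.95). Genes lowered by both numbered 0 (1.09), 0 (2.43) and 6 (4.34), and genes raised by both 1 (0.925), 2 (0.771) and 12 (4.24). Genes lowered by siIGF2BP2 thus exceeded the expected number both ways in DMSO and in TM, more so among genes raised by TM. The 2 treatments differed in the genes raised by siIGF2BP2. In DMSO these exceeded it both ways and do not show an opposition, and in TM they exceeded it only among genes lowered by TM. For siIGF2BP2 in TM an opposition to part of the TM response may exist among called genes, and whether it is particular to siIGF2BP2 stays open.

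The library labelled siIGF2BP2_DMSO replicate 2 stood apart from its group. A candidate explanation is counts from TM-treated libraries in its column, with an estimated 51.6% of counts having the TM profile (39.6% to 65.4%). Depth alone did not give such a share: the other 8 DMSO libraries, thinned to its total in 20 draws each, reached at most 7.96%, while its 5883 genes with a count lie just below the 5895 to 6278 of the other 17 libraries thinned in the same way. Counts spilled from the other 5 libraries of replicate 2 are a possible explanation, since their depth-weighted mix has 58.9% by the same estimate, but the mixes of replicate 1 (45.2%) and replicate 3 (59.6%) lie within the interval too. A library mixed up or pooled with TM-treated material stays open, and no biological explanation was tested.

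IGF2BP2 knockdown changed 615 genes in TM, against 50 for IGF2BP3 knockdown. Without siIGF2BP2_TM replicate 1, the library with the lowest total of that group, 455 genes passed, so that library alone is not the cause. With the 9 TM libraries thinned to the lowest total among them in 5 draws, siIGF2BP2 had 185 to 258 calls and siIGF2BP3 10 to 15, so the difference remained at equal depth. A larger effect of the IGF2BP2 siRNA on footprints, through its target or otherwise, stays open as a hypothesis, and differences between wells in how the siRNAs were taken up were not tested.

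The 71 genes lowered by IGF2BP3 knockdown in DMSO had a median log2 fold change of -0.73 in TM (matched lists -0.04 to 0.05), in libraries not shared with DMSO, which is consistent with an effect of the siRNA that recurs. They also differed between replicates of a group in which IGF2BP3 was not targeted: in siIGF2BP2_TM their median was 0.57 higher in replicate 1 than in replicates 2 and 3 (matched lists -0.11 to 0.10). In the libraries of siControl_DMSO, siControl_TM and siIGF2BP2_DMSO the medians against the other replicates lay between -0.06 and 0.08, and in the siIGF2BP3 groups themselves they were 0.13, -0.08 and 0.03 in DMSO and 0.18, 0.00 and -0.26 in TM for replicates 1, 2 and 3. Part of the fall may come from something that varies between libraries apart from the knockdown, which the tables do not separate from an effect of the siRNA.

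The TM response of raised genes was tested for a change with knockdown. For IGF2BP3 the mean log2 interaction over 260 genes was -0.0446 (SE between libraries 0.0225), inside the bound of 0.1 set beforehand, so a mean change of that size or more was not seen. For IGF2BP2 it was -0.107 (SE 0.0289) over 287 raised genes in 11 libraries, over 3 times its SE and past that bound by less than 1 SE, and -0.145 (SE 0.0813) over 100 lowered genes. These values mean a smaller rise of raised genes and a larger fall of lowered genes. The mean IGF2BP2 knockdown effect on raised genes was 0.101 in DMSO, from replicates 1 and 3 of siIGF2BP2_DMSO, and -0.0058 in TM. On lowered genes it was 0.019 in DMSO and -0.126 in TM. The exact permutation p-values of 0.06 and 0.08 come from exchanging libraries within a treatment, which carries effects of siRNA into the interaction, so they do not speak against a change, which stays open.

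The libraries of each comparison of 2 groups can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split and the highest of the others gave 3132 and 0 calls for TM in siControl, 86 and 0 for siIGF2BP3 in DMSO, 50 and 3 for siIGF2BP3 in TM, 136 and 12 for siIGF2BP2 in DMSO, 615 and 11 for siIGF2BP2 in TM, 2291 and 0 for TM in siIGF2BP3, 1500 and 523 for TM in siIGF2BP2, 253 and 0 for the knockdowns against each other in DMSO, and 537 and 1 in TM; in each, 1 split gave as many as the real one, the real one itself. The split with 523 calls for TM in siIGF2BP2 set the library labelled siIGF2BP2_DMSO replicate 2 with siIGF2BP2_TM replicates 2 and 3. For each interaction, 31 of 100 splits gave as many genes at an unadjusted p under 0.05 as the real one; the real and highest other counts were 749 and 2538 for siIGF2BP3, and 1165 and 3418 for siIGF2BP2. Splits with several times the real count point to a structure of the samples, as exchanging libraries within 1 treatment moves the effects of siRNA into the interaction, so these splits say nothing for or against chance.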
